A study of Rattus norvegicus with 36 samples.

How the data were processed

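Expression was measured in total RNA of lung tissue, bronchoalveolar lavage fluid cells (BALF cells) and blood from 12 male rats, 6 exposed to silica (15 mg/m3) and 6 to air (0 mg/m3), on 36 Illumina rat BeadChip arrays of 21792 probes. Groups and rat numbers came from the labels, which give the same 12 rats for each tissue. One blood sample of a silica rat is numbered 6 in its title and differently in its description, and its column was matched through the description. Its rat number was taken from its label, and the comparisons of blood with another tissue within rats rest on that number.

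Per the file headers, the deposited tables of the 3 tissues hold for each array the mean bead intensity of each probe and a detection p-value against negative-control beads. The intensity values were not normalized between arrays and never negative. A further deposited table holds the authors' processed values of the same arrays on a log2-like scale. Their medians lay between 7.61 and 7.62 in the lung, 7.52 in BALF cells and 7.21 to 7.22 in blood, and each array's values kept the order of its scanner values (rank correlation of 1). Above a raw signal of 1000 they followed log2 of the raw signal with slopes of 0.893 to 1.07, and the transformation of dim probes stays unknown. The submitters' processing notes name BeadStudio, lumi and limma, without versions. Which tool did which step, the slides and the scan dates are not given in the sources used here.

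The main values came from the intensity tables with neqc of limma 3.58.1 in R 4.3.3, within each tissue: normexp background correction with the negative-control level inferred from the detection p-values, an offset of 16, quantile normalization and log2. Probes with a detection p under 0.05 on at least 6 of 12 arrays were tested, 11399 in the lung, 9564 in BALF cells and 8044 in blood. Silica and air were compared with lmFit and eBayes, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. A log2 change near the detection floor understates the change in RNA. Differences between tissues were tested in the same way on each rat's difference of log2 values over probes tested in both. Fold change correlations were tested by relabelling the rats, with the tissues of a rat kept together.

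Probe names were updated through a RefSeq gene table of assembly GRCr8, used for names only: 9918 probes matched a current symbol, 4817 a synonym and 6940 neither, whose symbol in the file was kept, and 117 had no symbol. Renamed genes in the text are Jchain (Igj in the files), Gpihbp1 (RGD1564237), Tns2 (Tenc1), Lpar3 (Edg7), Rnase3 (Ear11), RT1-Da (H2-Ea), Ceacam4 (Ceacam10), Ccdc80 (Ssg1), Adgre5 (Cd97), C4b (C4-2), Cd177 (RGD1562941), Mzb1 (RGD1310251), Plin2 (Adfp), Bmal1 (Arntl), Bhlhe40 (Bhlhb2) and Bhlhe41 (Bhlhb3). A list holds 1 probe per gene, that of highest mean intensity.

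The tests, the 32 gene lists and the rule for named genes were fixed before the data were examined. The rule took, per tissue, the 12 largest rises and 12 largest falls among probes with adjusted p under 0.05, a named gene and all 6 silica arrays on one side of the air mean, or the 5 of smallest p where none passed. It also took up to 4 called members of each list by size, the 6 largest differences in each direction between tissues, and 10 genes fixed from knowledge of silica. Other members are named as values. The values of a single gene are not reported here, and it is left out of the counts of gene values across settings and of the arrays that lay apart. Lists of at least 3 measured members were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of a tissue, and again with an estimated correlation. The fry test, which does not compare a list with other genes, called 27 of 32 lung lists, 23 of 30 in BALF cells and 0 of 29 in blood as moving one way, and 29, 28 and 7 as changing in either direction.

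Alternatives were no background correction, a median shift in place of quantile normalization, no filter or detection on all 12 arrays, the authors' processed values, eBayes with trend and robust, array weights, the replicate number as a block, 1 probe per gene, a fold of at least 1.5, a joint model of the 3 tissues, normalized together, with the rat as a random block, and leaving out each array. Added after the data were seen were a shift to the median of probes detected on all 12 arrays, blood without its 3 arrays of lowest signal, the covariance of fold changes, narrower alveolar type 2 lists, for which the level of the members in BALF cells decided, and an exact permutation test of the mean level of each blood list, repeated for the called lists without those arrays, for the interferon list with a cell share covariate and for the lung alveolar type 2 list.

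Arrays of the same tissue and exposure group correlated at 0.981 or more, and no pair of arrays of a tissue held identical values. On simulated data with 200 changed probes, a 1.41-fold change was recovered for 95.5% of probes in the lung, 97% in BALF cells and 94% in blood, with 3.9%, 3.9% and 4.41% of calls false. The simulated values were independent normal noise around each probe's mean, without array effects, correlation between probes, background correction or normalization. These shares therefore check the fit and do not give the power on the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.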

Results

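Gene expression was measured on Illumina rat BeadChips, arrays of bead-borne oligonucleotide probes, in lung tissue, in cells recovered by bronchoalveolar lavage (BALF cells) and in blood of male rats of the Fischer strain. The rats had inhaled either crystalline silica at 15 mg/m3 for 6 h a day over 5 days or air with 0 mg/m3, and tissues were taken 44 weeks after the last exposure. Each of the 3 tissues was represented by 6 silica rats and 6 air rats, and by the labels the same 12 rats gave all 3 tissues, so that 36 arrays entered the comparisons. On the lung arrays 10974 to 11607 of 21792 probes were detected, on the BALF cell arrays 9229 to 9773 and on the blood arrays 7244 to 8861. The 95th percentile of the raw signal was 2276 to 2980 in the lung, 2031 to 2901 in BALF cells and only 514 to 1104 in blood. The lowest blood values belonged to air replicate 1 (514), silica replicate 6 (565) and air replicate 2 (682). The number of arrays, 6 per group, limits the precision of every value.

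The first comparison asked how gene expression in the lung differed between silica and air rats long after the exposure. Among named genes the largest rise was that of Retnla, a secreted protein of alternatively activated macrophages, which was 21.0-fold higher in silica lungs (log2 change 4.39 ± 0.29, SE, 6 rats per group). Spp1, which encodes the secreted phosphoprotein osteopontin, rose 12.3-fold (3.62 ± 0.36), Slc26a4, the anion exchanger pendrin, rose 12.2-fold (3.61 ± 0.25), and Mmp12, macrophage elastase, rose 6.41-fold (2.68 ± 0.23). The largest fall was that of Nr1d1, a nuclear receptor of the circadian clock, at -1.45 ± 0.20 (2.74-fold lower). Falls of the other named genes were smaller than 2-fold, from Gpihbp1, which anchors lipoprotein lipase at the capillary wall (-0.86 ± 0.15), to Rnase3, an eosinophil-associated ribonuclease (-0.65 ± 0.16).

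Of 11399 lung probes tested with limma, 942 were higher and 1078 lower in silica rats at an adjusted p under 0.05. Of these, 120 higher and 33 lower ones differed by at least 1.5-fold. After Retnla, Spp1, Slc26a4 and Mmp12, the largest rise was that of Ubd, a ubiquitin-like modifier (2.65 ± 0.52). The complement regulators Cfi (2.10 ± 0.20) and C4bpa (1.65 ± 0.17), the monocyte chemoattractant Ccl2 (1.98 ± 0.13) and the fatty acid binding protein Fabp4 (1.63 ± 0.21) followed. The 12 largest rises ended with the siderophore-binding protein Lcn2 (1.51 ± 0.16), the immunoglobulin joining chain Jchain (1.45 ± 0.19) and the immunoglobulin heavy chain Igh-1a (1.44 ± 0.30). Between Gpihbp1 and Rnase3 stood the falls of the amino acid transporters Slc38a5 (-0.81 ± 0.11) and Slc7a10 (-0.80 ± 0.094), the aminopeptidase Xpnpep2 (-0.75 ± 0.08) and the tensin Tns2 (-0.73 ± 0.093). The neuropeptide Npy (-0.72 ± 0.15), the DNA polymerase alpha subunit Pola2 (-0.69 ± 0.08) and vitronectin, Vtn (-0.69 ± 0.056), fell as well. So did the lysophosphatidic acid receptor Lpar3 (-0.68 ± 0.12) and Mamdc2 (-0.65 ± 0.11). These 24 genes had adjusted p between 5.56e-05 (Retnla) and 0.0196 (Rnase3), and in each the 6 silica arrays lay on the same side of the air mean. Among the 10 genes fixed in advance, Chi3l1, a chitinase-like protein (1.05 ± 0.10), and Ccl7 (0.94 ± 0.086) also rose. The arginase Arg1 (0.83 ± 0.10) and the surfactant protein Sftpd (0.61 ± 0.10) rose too, and no probe was matched to C3 by name.

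**Figure D1:**
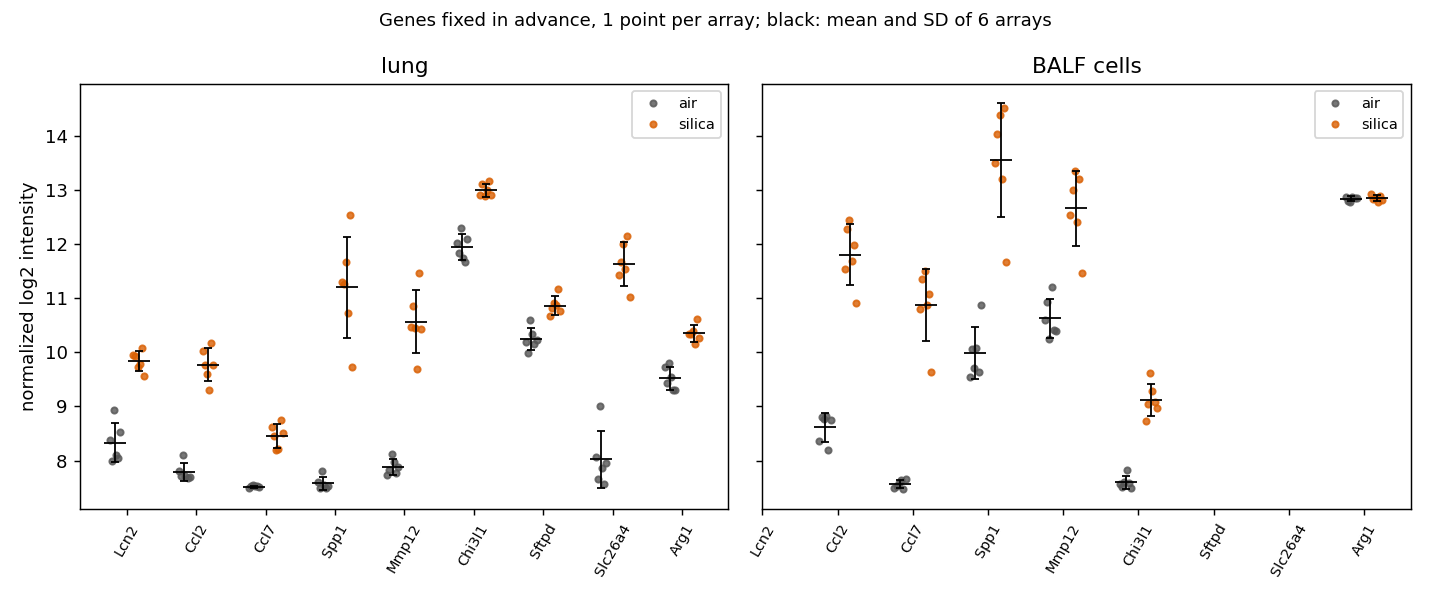
Normalized log2 intensity (vertical axis) of genes fixed in advance in the lung (left panel) and BALF cells (right panel), with 1 point per array, grey for air and orange for silica, and bars for the mean and SD of 6 arrays. Lung Spp1 averaged 7.58 in air and 11.20 in silica rats, Arg1 in BALF cells averaged 12.83 and 12.84, and Lcn2, Slc26a4 and Sftpd were detected on 0 arrays of BALF cells and have no points there.

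Several groups of immune genes were called higher in the lung. Complement genes rose with Cfi, C4bpa, the protease C1s (0.93 ± 0.17) and the component C4b (0.89 ± 0.12). Of 20 complement genes measured, 13 rose and 0 fell (13 and 0 adjusted over the list alone), with camera's adjusted p = 3.75e-10 and adjusted p = 0.00664 with an estimated correlation. Lysosomal genes included the cathepsins Ctsk (1.34 ± 0.23) and Ctss (0.77 ± 0.088), the macrophage protein Cd68 (0.85 ± 0.10) and Gpnmb (0.70 ± 0.073). Of 24 lysosomal genes measured, 16 rose and 0 fell (17 and 1 adjusted over the list alone), with camera's adjusted p = 3.75e-10 and adjusted p = 0.0488 with an estimated correlation. These 2 of the 24 called lung lists held with an estimated correlation, and the others did not. Chemokines besides Ccl2 that rose included Cxcl9, a ligand of activated T cells (1.22 ± 0.25), and Ccl3 (0.76 ± 0.10). Of 25 chemokines measured, 8 rose and 1 fell (10 and 1 adjusted over the list alone), with camera's adjusted p = 7.10e-06 and adjusted p = 0.0666 with an estimated correlation. Secreted innate defence genes had a median log2 change of 0.38, with haptoglobin, Hp, at 1.03 ± 0.13 and the endotoxin receptor Cd14 at 0.61 ± 0.11. Of 15 secreted innate defence genes measured, 8 rose and 0 fell (10 and 0 adjusted over the list alone), with camera's adjusted p = 2.20e-06 and adjusted p = 0.0598 with an estimated correlation. Markers of monocytes and recruited macrophages included the C1q chains C1qc (0.82 ± 0.19), C1qa (0.78 ± 0.15) and C1qb (0.75 ± 0.17), which also stand on the complement list. Of 18 monocyte and macrophage markers measured, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with camera's adjusted p = 2.02e-06 and adjusted p = 0.0666 with an estimated correlation. For C1qc, C1qa, Spp1, Ccl2 and Slc26a4, air replicate 3 lay above the other 5 air arrays, with a log2 intensity of 7.80 for Spp1. Subunits of the phagocyte oxidase that rose included Ncf1 (1.13 ± 0.11) and Cyba (0.50 ± 0.053). Of 8 phagocyte oxidase genes measured, 6 rose and 0 fell (6 and 2 adjusted over the list alone), with camera's adjusted p = 0.00041 and adjusted p = 0.0609 with an estimated correlation.

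MHC class II and antigen presentation genes that rose included RT1-Db1 (0.65 ± 0.09), RT1-Ba (0.63 ± 0.13) and Cd83, a marker of mature dendritic cells (0.67 ± 0.10). Of 13 antigen presentation genes measured, 7 rose and 0 fell (9 and 0 adjusted over the list alone), with camera's adjusted p = 2.20e-06 and adjusted p = 0.139 with an estimated correlation. Cell division genes rose with Ccnb2, a mitotic cyclin (0.71 ± 0.11), and Rrm2, a ribonucleotide reductase subunit (0.43 ± 0.063). Of 27 cell division genes measured, 15 rose and 0 fell (20 and 0 adjusted over the list alone), with camera's adjusted p = 2.79e-09 and adjusted p = 0.1 with an estimated correlation. Jchain and Mzb1, a plasma cell protein (0.37 ± 0.053), were among the B and plasma cell markers that rose. Of 10 B and plasma cell markers measured, 3 rose and 0 fell (3 and 0 adjusted over the list alone), with camera's adjusted p = 0.000141 and adjusted p = 0.0598 with an estimated correlation. Enzymes of sterol synthesis such as Fdps (0.33 ± 0.068) and Idi1 (0.28 ± 0.076) rose. Of 19 sterol and fatty acid synthesis genes measured, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with camera's adjusted p = 4.06e-06 and adjusted p = 0.0917 with an estimated correlation. Lipid-handling genes that rose included Fabp4, Plin2 (0.43 ± 0.043) and Trem2 (0.48 ± 0.093). Of 19 lipid-handling genes measured, 8 rose and 1 fell (12 and 2 adjusted over the list alone), with camera's adjusted p = 3.65e-05 and adjusted p = 0.0598 with an estimated correlation. Alternative macrophage activation genes were called higher with Retnla, Arg1 and the mannose receptor Mrc1 (0.51 ± 0.13). Of 14 alternative activation genes measured, 7 rose and 4 fell (8 and 4 adjusted over the list alone), with camera's adjusted p = 0.0106 and adjusted p = 0.0609 with an estimated correlation. Neutrophil markers were called higher with Cd177 (1.28 ± 0.19) and Trem1 (0.31 ± 0.046) among the members that rose, but the list's median of -0.0021 differed in sign from its mean of 0.27. Of 18 neutrophil markers measured, 5 rose and 0 fell (5 and 0 adjusted over the list alone), with camera's adjusted p = 0.006 and adjusted p = 0.265 with an estimated correlation.

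Surfactant and alveolar type 2 genes that rose included Muc1 (0.77 ± 0.093), the protease Ctsh (0.76 ± 0.085) and Sftpd, while Sftpc and Sftpb had log2 changes of 0.053 and -0.062. Of 14 alveolar type 2 genes measured, 7 rose and 0 fell (9 and 0 adjusted over the list alone), with camera's adjusted p = 4.06e-06 and adjusted p = 0.117 with an estimated correlation. Antioxidant genes were led by the haem oxygenase Hmox1 (1.25 ± 0.10) and Sod2 (0.87 ± 0.072). Of 23 antioxidant genes measured, 9 rose and 2 fell (9 and 4 adjusted over the list alone), with camera's adjusted p = 0.006 and adjusted p = 0.1 with an estimated correlation. Inflammasome and NF-kB cytokine genes that rose included Il18 (0.76 ± 0.12) and Il1rn (0.38 ± 0.06). Of 18 inflammasome and cytokine genes measured, 5 rose and 0 fell (5 and 0 adjusted over the list alone), with camera's adjusted p = 0.006 and adjusted p = 0.117 with an estimated correlation. Among alveolar macrophage markers Fabp4 rose, and Car4 (-0.58 ± 0.07) and Rnase3 fell. Of 11 alveolar macrophage markers measured, 5 rose and 2 fell (6 and 2 adjusted over the list alone), with camera's adjusted p = 0.0169 and adjusted p = 0.135 with an estimated correlation. Mast cell markers were called higher with Mcpt10 (0.33 ± 0.067). Of 11 mast cell markers measured, 7 rose and 1 fell (7 and 2 adjusted over the list alone), with camera's adjusted p = 0.00866 and adjusted p = 0.135 with an estimated correlation. With each array shifted to the median of the probes detected on all arrays, a setting added after the data were seen, the calls of the inflammasome, antioxidant, alveolar macrophage and mast cell lists ended. With only the probes detected on all 12 arrays the mast cell list turned to a median of -0.12.

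Several lists of structural cell markers were called lower in silica lungs, as were the collagen, immediate early and erythroid lists. Endothelial markers fell with a median log2 change of -0.44, including the von Willebrand factor Vwf (-0.57 ± 0.088), Ramp2 (-0.50 ± 0.077), the receptor Tie1 (-0.48 ± 0.054) and Acvrl1 (-0.47 ± 0.08). Of 14 endothelial markers measured, 0 rose and 10 fell (0 and 13 adjusted over the list alone), with camera's adjusted p = 2.79e-09 and adjusted p = 0.0598 with an estimated correlation. Collagen and fibrosis genes that fell included Col4a1 (-0.50 ± 0.08), Col14a1 (-0.52 ± 0.14) and Postn (-0.45 ± 0.11), and Spp1, which is no collagen, was the only member that rose. Of 32 collagen and fibrosis genes measured, 1 rose and 14 fell (1 and 18 adjusted over the list alone), with camera's adjusted p = 3.65e-05 and adjusted p = 0.0598 with an estimated correlation. Smooth muscle and fibroblast markers fell with Mfap4 (-0.45 ± 0.076) and the myosin Myh11 (-0.43 ± 0.12). Of 12 smooth muscle and fibroblast markers measured, 0 rose and 5 fell (0 and 8 adjusted over the list alone), with camera's adjusted p = 0.000418 and adjusted p = 0.0854 with an estimated correlation. Alveolar type 1 markers fell with the caveolin Cav1 (-0.43 ± 0.07) and the water channel Aqp5 (-0.42 ± 0.089). Of 11 alveolar type 1 markers measured, 0 rose and 5 fell (0 and 8 adjusted over the list alone), with camera's adjusted p = 0.000103 and adjusted p = 0.0913 with an estimated correlation. Immediate early genes were called lower, with Ier2 (-0.57 ± 0.15) and Btg2 (-0.36 ± 0.10) lower but Egr2 higher (0.59 ± 0.081). Of 18 immediate early genes measured, 2 rose and 3 fell (2 and 4 adjusted over the list alone), with camera's adjusted p = 0.0393 and adjusted p = 0.465 with an estimated correlation. This call ended without air replicate 1, 2, 3 or 6 or silica replicate 1, 2, 3 or 5, with adjusted p from 0.0509 to 0.125. Erythroid markers were called lower with Gypc at -0.28 ± 0.04. Of 12 erythroid markers measured, 0 rose and 3 fell (0 and 6 adjusted over the list alone), with camera's adjusted p = 0.006 and adjusted p = 0.125 with an estimated correlation. This call ended with the shift to the median of detected probes, where Slc4a1 turned to 0.091. Ciliated, club and goblet, T and NK, interferon, p53 and cell death, epithelial transport, protease and platelet lists did not pass. Their adjusted p lay between 0.0592 (platelets) and 0.431 (interferon). In the protease list, where 4 of 19 members rose and 2 fell, the median of -0.0099 and the mean of 0.18 differed in sign.

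The test of each probe was limma's moderated test on quantile-normalized log2 intensities with Benjamini-Hochberg adjustment. With only a median shift of each array 37 probes were higher and 40 lower, and Fabp4, Gpihbp1, Igh-1a, Jchain, Lpar3, Mamdc2, Rnase3, Slc38a5 and Ubd no longer passed. With the shift to the median of detected probes 322 were higher and 659 lower (32.8% higher), against 942 and 1078 in the quantile-normalized values, and Vtn did not pass in the joint model of the 3 tissues.

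**Figure D2:**
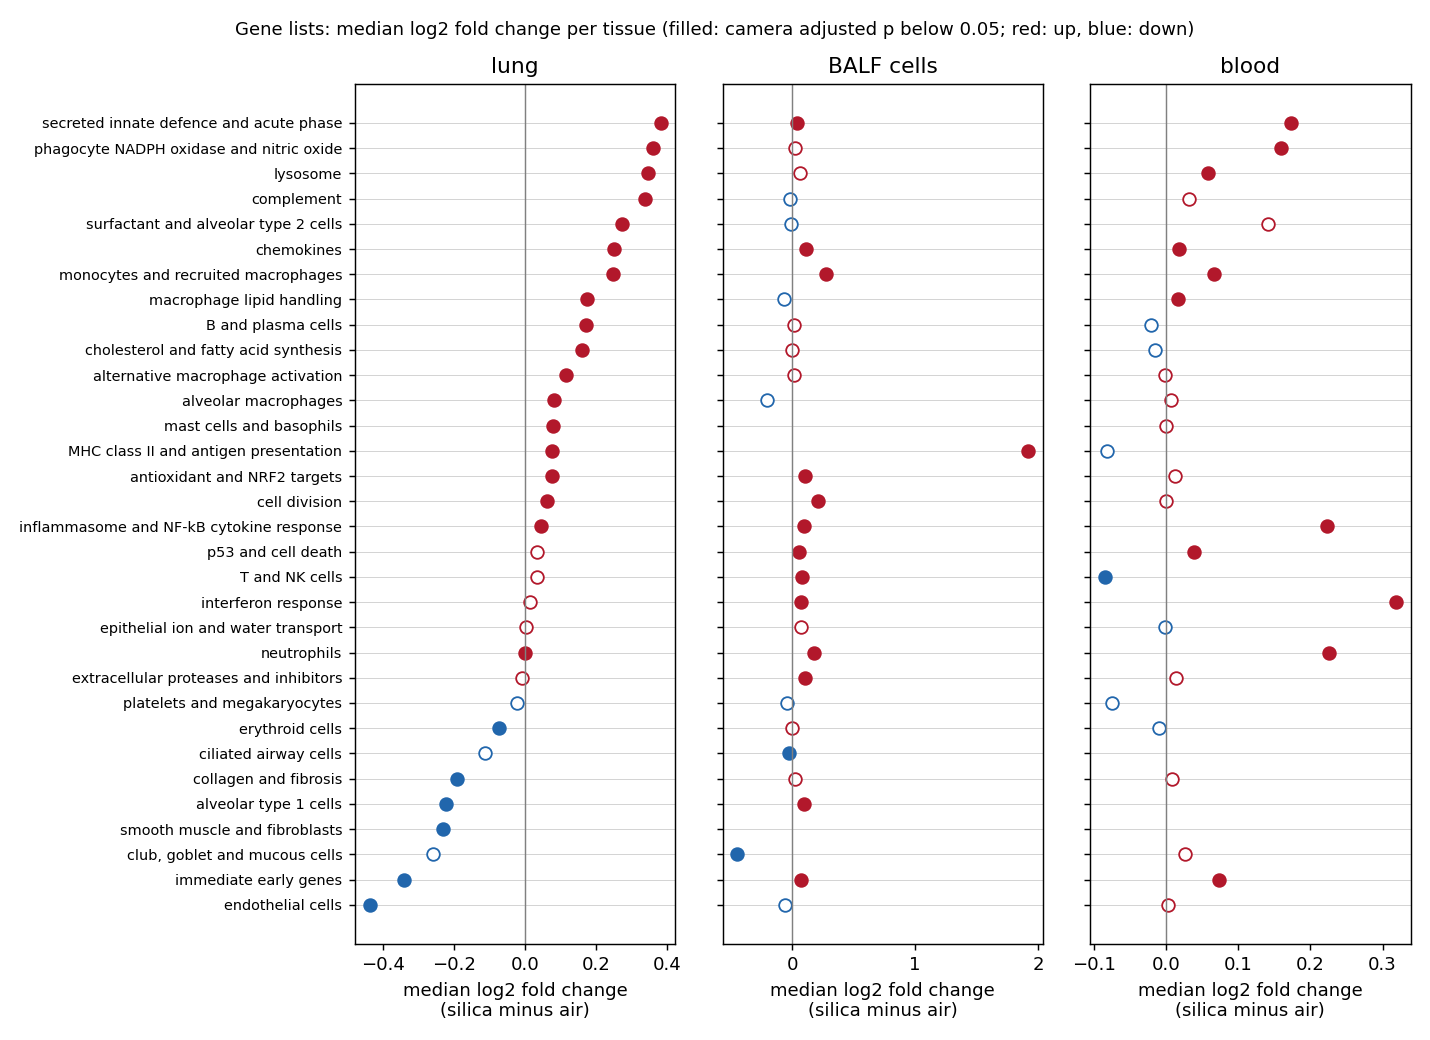
Median log2 fold change, silica minus air (horizontal axis), of each of 32 gene lists (vertical axis) in 3 tissues, filled where camera called the list at an adjusted p under 0.05 and coloured red for up and blue for down, with no point where fewer than 3 members were measured. Endothelial genes had the lowest lung median (-0.44) and MHC class II and antigen presentation genes the highest BALF cell median (1.92).

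In BALF cells, the same question was asked of the cells washed from the airspaces. The values are those of all lavage cells together. A change within cells was not told apart from a change in the mix of cells. Apoe, an apolipoprotein made by macrophages, rose 27.3-fold in silica rats (4.77 ± 0.29, SE, 6 rats per group), and Spp1 rose 11.8-fold (3.56 ± 0.45). The MHC class II genes RT1-Db1 and RT1-Da rose 10.7-fold and 8.94-fold (3.42 ± 0.31 and 3.16 ± 0.21). The chemokines Ccl7 and Ccl2 rose by 3.30 ± 0.26 and 3.19 ± 0.24. Among named genes the largest falls were those of the gluconeogenic enzyme Fbp1 (-2.23 ± 0.12, 4.70-fold lower), the lipoxygenase Alox15 (-1.97 ± 0.17) and the copper ferroxidase Heph (-1.93 ± 0.12).

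Of 9564 BALF cell probes tested with limma, 1458 were higher and 1729 lower, and 147 and 125 of these differed by at least 1.5-fold. Other large rises were those of the homeodomain protein Hopx (3.31 ± 0.11), the decoy interleukin-1 receptor Il1r2 (2.78 ± 0.11) and Slfn3 (2.77 ± 0.13). The protease inhibitor Slpi (2.21 ± 0.10), Ceacam4 (2.17 ± 0.12) and the invariant chain Cd74 (2.13 ± 0.24) rose as well. Other large falls were those of the lectin-like receptor Ly49s4 (-1.86 ± 0.10), Gipc2 (-1.73 ± 0.12), the palmitoyltransferase Zdhhc2 (-1.70 ± 0.084) and Ccdc80 (-1.28 ± 0.10). The tachykinin precursor Tac1 (-1.25 ± 0.088), Tmem176b (-1.24 ± 0.12) and the keratin Krt19 (-1.23 ± 0.13) fell, as did the calcium channel subunit Cacnb3 (-1.21 ± 0.084) and the platelet factor Pf4 (-1.18 ± 0.13). These 24 genes had adjusted p from 1.94e-08 (Hopx) to 0.000128 (Spp1) and all 6 silica arrays on one side of the air mean. Mmp12 rose 4.07-fold (2.03 ± 0.30) and Chi3l1 2.87-fold (1.52 ± 0.12), while Arg1 had a log2 change of 0.0099 ± 0.026 that did not pass.

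MHC class II and antigen presentation genes had a median log2 change of 1.92 in BALF cells, with RT1-Ba at 1.92 ± 0.27. Of 7 antigen presentation genes measured, 4 rose and 0 fell (4 and 0 adjusted over the list alone), with camera's adjusted p = 0.0013 and adjusted p = 0.251 with an estimated correlation. Silica replicate 6 stood above the other 5 silica arrays for RT1-Db1 (log2 intensity 13.18), RT1-Da (14.30), Cd74 (10.93) and RT1-Ba (10.86). Cell division genes that rose included Rrm2 (0.89 ± 0.13) and the ubiquitin conjugase Ube2c (0.72 ± 0.057). Of 30 cell division genes measured, 22 rose and 1 fell (24 and 1 adjusted over the list alone), with camera's adjusted p = 5.72e-10 and adjusted p = 0.251 with an estimated correlation. Among BALF cell chemokines Cxcl1 fell (-1.14 ± 0.094), while Ccl7, Ccl2 and Ccl5 (1.49 ± 0.37) rose, and the call ended with only the probes detected on all 12 arrays. Of 17 chemokines measured, 8 rose and 2 fell (8 and 2 adjusted over the list alone), with camera's adjusted p = 0.0196 and adjusted p = 0.213 with an estimated correlation. Neutrophil markers rose with Il1r2, the calprotectin subunit S100a8 (1.41 ± 0.18) and the integrin Itgam (0.75 ± 0.056), and air replicate 4 stood above the other air arrays for S100a8 (7.96). Of 14 neutrophil markers measured, 10 rose and 1 fell (10 and 2 adjusted over the list alone), with camera's adjusted p = 2.78e-05 and adjusted p = 0.213 with an estimated correlation. T and NK cell markers rose with Cd3g, a chain of the T cell receptor complex (1.19 ± 0.15), Ccr7 (0.63 ± 0.055) and Lat (0.63 ± 0.14). Of 20 T and NK markers measured, 14 rose and 0 fell (15 and 1 adjusted over the list alone), with camera's adjusted p = 9.48e-06 and adjusted p = 0.268 with an estimated correlation. For Cd3g (9.46) and Ccl5 (10.80), silica replicate 6 again stood above its group. Monocyte markers such as Cd14 (1.77 ± 0.15) and Fcgr2b (1.27 ± 0.11) rose while Fcgr3a fell (-0.78 ± 0.13). Of 15 monocyte and macrophage markers measured, 9 rose and 2 fell (9 and 2 adjusted over the list alone), with camera's adjusted p = 0.000381 and adjusted p = 0.121 with an estimated correlation. Interferon response genes such as Ifit1 (0.88 ± 0.082) and Irf7 (0.88 ± 0.085) rose. Of 23 interferon response genes measured, 9 rose and 2 fell (10 and 2 adjusted over the list alone), with camera's adjusted p = 0.00998 and adjusted p = 0.273 with an estimated correlation.

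Inflammasome and NF-kB cytokine genes that rose in BALF cells included Il1b, an inflammatory cytokine (1.13 ± 0.17), and Nfkbia, an inhibitor of NF-kB (0.83 ± 0.059). Of 16 inflammasome and cytokine genes measured, 7 rose and 2 fell (8 and 2 adjusted over the list alone), with camera's adjusted p = 0.00998 and adjusted p = 0.255 with an estimated correlation. Proteases and inhibitors were called higher with Slpi, Mmp12 and Mmp7 (1.14 ± 0.15). Of 11 protease and inhibitor genes measured, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with camera's adjusted p = 0.00367 and adjusted p = 0.213 with an estimated correlation. Secreted innate defence genes were called higher with Slpi, Cd14 and Chi3l1. Of 11 secreted innate defence genes measured, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with camera's adjusted p = 0.0128 and adjusted p = 0.268 with an estimated correlation.

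Ddit3, a stress-induced transcription factor of the p53 and cell death list, rose by 1.63 ± 0.074. Of 15 p53 and cell death genes measured, 7 rose and 2 fell (7 and 2 adjusted over the list alone), with camera's adjusted p = 0.0107 and adjusted p = 0.121 with an estimated correlation. Immediate early genes such as Ier3 (0.95 ± 0.08) and Junb (0.69 ± 0.088) rose. Of 17 immediate early genes measured, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with camera's adjusted p = 0.0196 and adjusted p = 0.259 with an estimated correlation. This call ended with the shift to the median of detected probes and without silica replicate 4 (adjusted p = 0.0539). Antioxidant genes such as Gclc rose (0.58 ± 0.069), while catalase, Cat, fell (-0.62 ± 0.079), and this call ended with either median shift. Of 22 antioxidant genes measured, 10 rose and 2 fell (11 and 3 adjusted over the list alone), with camera's adjusted p = 0.00998 and adjusted p = 0.121 with an estimated correlation. The alveolar type 1 list was called higher on 3 measured members, of which Hopx and Pdpn (0.10 ± 0.012) rose, and this call ended with no filter on dim probes. Of 3 alveolar type 1 markers measured, 2 rose and 0 fell (2 and 1 adjusted over the list alone), with camera's adjusted p = 0.0293 and adjusted p = 0.213 with an estimated correlation. Club and goblet cell markers fell, among them the secretoglobins Scgb3a1 (2.01-fold lower) and Scgb1a1 (-0.89 ± 0.19). Of 10 club and goblet markers measured, 0 rose and 5 fell (0 and 7 adjusted over the list alone), with camera's adjusted p = 0.00887 and adjusted p = 0.284 with an estimated correlation. Ciliated cell markers were called lower with a median of -0.029. Of 8 ciliated cell markers measured, 0 rose and 5 fell (0 and 5 adjusted over the list alone), with camera's adjusted p = 0.0293 and adjusted p = 0.251 with an estimated correlation. This call ended without air replicate 4 (adjusted p = 0.0571), with only the probes detected on all 12 arrays and with the shift to the median of detected probes. None of the 16 called lists held with an estimated correlation, where the smallest adjusted p was 0.121.

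Of the BALF cell lists that did not pass, alveolar macrophage markers had a median of -0.20, with 2 of 11 members higher and 5 lower. Among the members that fell were Pparg (-0.54 ± 0.10) and Mrc1 (-0.47 ± 0.069). Among members of the collagen list Spp1 and fibronectin, Fn1 (1.93 ± 0.18), rose, and in the sterol synthesis list the desaturase Scd rose (1.81 ± 0.16). The lysosome, complement, lipid handling, alternative activation, phagocyte oxidase, alveolar type 2, endothelial, B and plasma cell, epithelial transport, erythroid and platelet lists did not pass either. Adjusted p of all these lists lay between 0.113 (collagen) and 0.936 (complement and alveolar type 2). Median and mean differed in sign for macrophage lipid handling (-0.069 and 0.21), alveolar type 2 cells (-0.0099 and 0.14) and sterol synthesis (-0.0058 and 0.13). They also did for the phagocyte oxidase (0.022 and -0.03). For erythroid cells both were negative (-0.0011 and -0.34) while the test's direction was up. The smooth muscle and mast cell lists had fewer than 3 measured members and were not tested.

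BALF cell probes were tested as in the lung. A median shift of each array gave 275 higher and 207 lower, and the shift to the median of detected probes gave 513 and 721, against 1458 and 1729 in the quantile-normalized values, so that 57.1% of calls were higher with the median shift and fewer than 50% in the quantile-normalized values.

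In blood, the comparison asked whether the same rats differed in circulating cells. With limma, 0 of 8044 probes were higher and 0 lower at an adjusted p under 0.05, 1072 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0786. The 5 probes of smallest p included the mitochondrial ribosomal gene Mrps30 (-0.20 ± 0.026, adjusted p = 0.0786), the chemokine receptor Ccr6 (-0.48 ± 0.077) and the diacylglycerol kinase Dgka (-0.40 ± 0.069). The others were the ubiquitin ligase Rnf125 (-0.28 ± 0.05) and the mitochondrial gene Ndufa10 (-0.13 ± 0.023), and all but Mrps30 had an adjusted p of 0.18. Chi3l1 had a log2 change of 0.76 ± 0.33 and adjusted p = 0.361, Ccl2 0.0099 ± 0.017 and Arg1 -0.18 ± 0.19, and Spp1, Mmp12, Lcn2, Ccl7, Slc26a4 and Sftpd were detected on 0 of 12 blood arrays.

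Camera called 11 blood lists higher and 1 lower although 0 of their members passed over all probes. The interferon response list had the largest median, 0.32. Of 22 interferon response genes measured in blood, 14 higher and 0 lower members passed adjusted over the list alone (camera's adjusted p = 5.90e-12, adjusted p = 0.31 with an estimated correlation). Neutrophil markers had a median of 0.23. Of 15 neutrophil markers measured in blood, 0 higher and 0 lower members passed adjusted over the list alone (camera's adjusted p = 1.41e-05, adjusted p = 0.32 with an estimated correlation). T and NK cell markers were called lower, with a median of -0.085. Of 22 T and NK markers measured in blood, 2 higher and 9 lower members passed adjusted over the list alone (camera's adjusted p = 0.00561, adjusted p = 0.517 with an estimated correlation). Also called higher were the inflammasome list (0.22), secreted innate defence genes (0.17) and the phagocyte oxidase list (0.16). Of 12 inflammasome and cytokine genes measured in blood, 3 higher and 0 lower members passed adjusted over the list alone (camera's adjusted p = 2.25e-07, adjusted p = 0.32 with an estimated correlation). Of 9 secreted innate defence genes measured in blood, 1 higher and 0 lower members passed adjusted over the list alone (camera's adjusted p = 0.00176, adjusted p = 0.324 with an estimated correlation). Of 6 phagocyte oxidase genes measured in blood, 0 higher and 0 lower members passed adjusted over the list alone (camera's adjusted p = 0.00176, adjusted p = 0.324 with an estimated correlation). Lists called higher with medians under 0.1 were those of monocytes, immediate early genes, lysosome, chemokines, p53 and macrophage lipid handling. Of 10 monocyte and macrophage markers measured in blood, 2 higher and 0 lower members passed adjusted over the list alone (camera's adjusted p = 0.000119, adjusted p = 0.31 with an estimated correlation). Of 16 immediate early genes measured in blood, 2 higher and 0 lower members passed adjusted over the list alone (camera's adjusted p = 4.52e-06, adjusted p = 0.31 with an estimated correlation). Of 21 lysosomal genes measured in blood, 0 higher and 0 lower members passed adjusted over the list alone (camera's adjusted p = 0.00631, adjusted p = 0.324 with an estimated correlation). Of 11 chemokines measured in blood, 3 higher and 0 lower members passed adjusted over the list alone (camera's adjusted p = 0.0134, adjusted p = 0.32 with an estimated correlation). Of 11 p53 and cell death genes measured in blood, 4 higher and 1 lower members passed adjusted over the list alone (camera's adjusted p = 0.0309, adjusted p = 0.32 with an estimated correlation). Of 14 lipid-handling genes measured in blood, 0 higher and 0 lower members passed adjusted over the list alone (camera's adjusted p = 0.0377, adjusted p = 0.351 with an estimated correlation). The lists of B and plasma cells, alveolar type 2 genes, complement, cell division, erythroid cells, platelets and the others tested did not pass. Their adjusted p lay between 0.0579 (B and plasma cells, alveolar type 2) and 0.892 (epithelial transport). Median and mean differed in sign for endothelial cells (0.0035 and -0.0095) and alternative macrophage activation (-0.001 and 0.13). The alveolar type 1, ciliated and smooth muscle lists had fewer than 3 measured members.

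All 12 blood lists lost their call with an estimated correlation. The calls of T and NK cells (adjusted p = 0.109), p53 (0.1) and macrophage lipid handling (0.0606) ended without silica replicate 6 alone, those of p53 (0.0718) and lipid handling (0.123) without air replicate 1, and that of lipid handling without air replicate 2 (0.108) or silica replicate 2 (0.0676). With the 3 arrays of lowest signal left out, a setting added after the data were seen, 0 probes passed, and the calls of T and NK cells (adjusted p = 0.128), p53 (0.219) and lipid handling (0.468) ended, with medians of -0.05, 0.043 and 0.013 against -0.085, 0.038 and 0.016 with all arrays. The medians of other lists were then 0.27 for the interferon, 0.14 for the inflammasome, 0.12 for the neutrophil, 0.087 for the secreted innate defence, 0.078 for the phagocyte oxidase and 0.022 for the lysosome list, and the alveolar type 2 list was called higher (adjusted p = 0.0345) and the platelet list lower (0.0394). The chemokine, T and NK and lipid handling calls also ended with either median shift, that of p53 with the median shift of each array and that of monocytes with the shift to the median of detected probes. Without a filter the chemokine and secreted innate defence calls ended, and with only the probes detected on all 12 arrays that of lipid handling did. The joint model of the 3 tissues called 596 blood probes higher and 388 lower, the fit without air replicate 2 called 1 probe lower, and each of the other fits tried called 0. The joint model also normalized all 36 arrays together and pooled the spread over tissues. Its correlation within a rat was 0.00584, and its blood log2 changes correlated with the main ones at r = 0.842.

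The silica effect was compared between tissues within rats. A higher effect means here a higher signed log2 change, which can also be a smaller fall. Apoe, Hopx, RT1-Da, RT1-Db1, Slfn3 and Il1r2 had a higher effect in BALF cells than in the lung, with a difference of -4.35 ± 0.41 for Apoe, whose lung change was 0.42 ± 0.16, and of -3.42 ± 0.11 for Hopx. Cfi had a higher effect in the lung (difference 2.15 ± 0.19), as did Ubd (1.65 ± 0.37), and so did Fbp1, Ly49s4, Gipc2 and Heph, which fell in BALF cells. Limma called 1116 of 9131 probes with a higher and 937 with a lower effect in the lung than in BALF cells. The 215 probes called in opposite directions in the separate tissues all had a called difference, which opposite calls make nearly certain. Between lung and blood, 382 of 7555 probes had a higher and 331 a lower effect in the lung. These were led by Retnla (4.38 ± 0.30, adjusted p = 7.77e-05), Ubd (2.62 ± 0.51) and Ccl2 (1.97 ± 0.14). On the other side stood Mal (-1.28 ± 0.32), Adgre5 (-1.15 ± 0.26) and the interferon-response gene Rtp4 (-1.01 ± 0.18). For Rtp4 neither the lung change (-0.18, adjusted p = 0.186) nor the blood change (0.82, adjusted p = 0.18) passed by itself in limma's test. Between BALF cells and blood, 792 of 7180 probes had a higher and 828 a lower effect in BALF cells. The largest differences were those of Apoe (5.06 ± 0.42) and RT1-Db1 (3.53 ± 0.44) and, with a lower effect in BALF cells, of Alox15 (-1.90 ± 0.14) and Ly49s4 (-1.89 ± 0.10). With a median shift in place of quantile normalization these counts were 46 and 88, 3 and 1, and 29 and 25.

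The last comparison asked how far the tissues changed alike. Of probes tested in both lung and BALF cells, 334 were higher in both, against 128 for independent lists, and 216 were lower in both, against 119. Another 124 were higher in the lung and lower in BALF cells, against 153, and 91 lower in the lung and higher in BALF cells, against 99.3. The same rats gave both tissues, for which these numbers for independent lists make no allowance. The log2 changes of lung and BALF cells correlated across 9131 probes with Pearson's r = 0.296 and Spearman's rho = 0.238, those of lung and blood with r = 0.0635 (rho = 0.0821) and those of BALF cells and blood with r = 0.107 (rho = -0.0077). Probes are not independent replicates. Over all 924 relabellings of the rats, with the tissues of a rat kept together, the median r was 0.204, -0.0123 and 0.038 for these pairs. In the exact one-sided permutation test over them, r did not pass for lung and BALF cells (p = 0.16), lung and blood (p = 0.143) or BALF cells and blood (p = 0.173), with 0.00216 as the smallest p possible. The covariance of the changes, a statistic chosen after the data were seen, was 0.0126 (exact p = 0.00216, the smallest possible), 0.00142 (exact p = 0.00433) and 0.0032 (exact p = 0.00649) for the same pairs, against medians of 0.00123, -7.99e-05 and 0.000198 over the relabellings. Across the 6 silica rats, the mean chemokine level in the lung and in BALF cells had r = -0.215 and rho = -0.0286 (exact permutation p = 0.704 and 1), and r = -0.518 over 4 rats without the 2 farthest from the median. Lung and blood chemokines had r = -0.574 and rho = -0.6 (exact p = 0.243 and 0.242), and r = 0.0223 without those 2 rats. For secreted innate defence genes, lung and BALF cells had r = -0.276 and rho = 0.2 (exact p = 0.596 and 0.714, r = 0.957 over 4 rats), and lung and blood r = 0.0683 and rho = -0.0286 (exact p = 0.919 and 1, r = 0.523 over 4 rats). None of the 4 relations passed, with Benjamini-Hochberg adjusted p of at least 0.919 for r and 0.967 for rho.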

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

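Of the tests below, those of the share of lung tissue cells, of the time of day, of the 3 blood arrays of lowest signal and of the mean levels of blood lists, with their use to judge the shift in blood, were chosen only after the results were seen. The lower markers of structural cells in silica lungs are the first pattern weighed: median log2 changes were -0.44 for endothelial, -0.23 for smooth muscle and fibroblast, -0.22 for alveolar type 1, -0.11 for ciliated and -0.26 for club and goblet markers, of which the ciliated and club lists were not called and the other 3 lost their call with an estimated correlation (adjusted p = 0.0598, 0.0854 and 0.0913). Of the 2 most abundant genes of each list, Ramp2 (13.28 in air, 12.78 in silica lungs), Col1a2 (-0.23), Tcf21 (13.27 and 12.93), Tppp3 (-0.42) and Aldh1a1 (-0.34) fell and Tekt2 (0.44) and, of the alveolar type 2 list, Sftpa1 (0.24) rose, while Sftpb (-0.062), Cldn5 (-0.30), Hopx (-0.11), Pdpn (-0.19) and Scgb1a1 (0.088) did not pass, and 1 of 14 endothelial, 4 of 12 smooth muscle and fibroblast and 1 of 9 club and goblet members stand on another list. A lower share of all lung tissue cells as the whole cause is argued against by the alveolar type 2 list, whose median was 0.27 (95% bootstrap interval 0.069 to 0.45 over 14 members, none on another list, and 0.022 to 0.52 over the 10 members below 8 or not measured in BALF cells), whose 7 members not measured in BALF cells had a median of 0.053 (-0.0081 to 0.45) and a mean level higher by 0.22 (exact p = 0.00866), and whose members moved up on balance in the fry test (adjusted p = 0.00104), although its camera call was lost with an estimated correlation (adjusted p = 0.117) and its median was 0.095 with a median shift. The choice of normalization as the cause is argued against by the endothelial median, which came no closer to 0 than -0.35 over 4 other normalizations. Each of these also brought the arrays to a common level, so they cannot tell a fall from a fall relative to other RNA. Fewer endothelial, smooth muscle or alveolar type 1 cells, or less RNA from each, may underlie the pattern and stay open, with a change in the type 2 cells themselves and the silica exposure, which no test here addresses.

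The second pattern is a set of clock genes in silica lungs, with Nr1d1 at -1.45 ± 0.20 and Bhlhe41 at 0.92 ± 0.12, which kept its direction but not its call with a median shift (0.69, adjusted p = 0.143). The choice of background correction or normalization as the cause of the Nr1d1 fall is argued against, since Nr1d1 came no closer to 0 than -1.26 over 4 others (largest limma adjusted p = 0.00611). A different time of day of tissue collection in silica and air rats could give such changes, and it cannot be told apart from the exposure. The 4 clock genes called in the lung and well measured in BALF cells of the same rats had a median BALF cell change, signed by the lung direction, of -0.057 but went both ways, from -0.32 (Bhlhe40) to 0.27 (Cry1), which decides nothing. Per2, left out since its lung change of -0.49 did not pass, was called higher in BALF cells (0.35, limma's adjusted p = 0.038), but not with either median shift. Nr1d1 was called lower in BALF cells too (-0.0503, adjusted p = 0.00874, 6 of 6 silica arrays below the air mean), with -0.30 without background correction (adjusted p = 0.00183) and no call with either median shift, but it lay near background there, and the times of collection, not given in the sources used here, and the exposure stay open, untested.

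The third pattern is the shift of blood gene lists with 0 probes called, led by the interferon list (median 0.32), whose mean level was higher by 0.32 in silica rats (exact permutation p = 0.00649, two-sided, over 924 relabellings), but it had been picked as the list of largest median, the p adjusted over the 29 lists was 0.0471 (4 lists passed, the others being chemokines, monocytes and immediate early genes), and 8 of 100 splits of the rats gave as many called lists (12 in the real split, 17 in the highest other), so chance is not excluded for the number of lists. Without the 3 arrays of lowest signal the interferon list kept its call, with a median of 0.27 (95% bootstrap interval over its members 0.084 to 0.35). Its mean level was 0.25 higher over the 9 other rats (exact p = 0.00794, the smallest possible). The chemokine, monocyte and immediate early lists kept their calls as well. Their medians were small, at 0.02, 0.059 and 0.06 against 0.018, 0.067 and 0.074 with all arrays. The largest exact p of the 4 lists, adjusted over the 12 called lists, was 0.0476. Those 12 lists had been called from the same rats, so this p is no independent support. The sizes kept argue against those arrays as the whole cause of the shift in these 4 lists. With all arrays, though, these 4 lists lost camera's call with an estimated correlation (adjusted p from 0.31 to 0.32). The chemokine call also ended with either median shift, and the monocyte call with the shift to the median of detected probes. Of the other 8, 3 lost their call, with medians going from -0.085 to -0.05 for T and NK cells (95% interval without the arrays -0.13 to 0.20), from 0.038 to 0.043 for p53 (-0.01 to 0.073) and from 0.016 to 0.013 for lipid handling (-0.0039 to 0.071), each at least 0.592 times its value before. Their mean levels, however, turned sign for T and NK cells (-0.071 to 0.044) and lipid handling (0.027 to -0.037), and went from 0.058 to 0.035 for p53. The lysosome and phagocyte oxidase medians, with their calls kept, went from 0.059 to 0.022 and from 0.16 to 0.078. The inflammasome and neutrophil lists kept their calls too, with medians of 0.14 (95% interval 0.076 to 0.29) and 0.12 (0.046 to 0.34) without the arrays. Their exact p of the mean level, adjusted over the 12 called lists, was 0.0762 and 0.127. The secreted innate defence list kept its call at a median of 0.087 (-0.14 to 0.34). In none of these 8 lists did call, interval and adjusted exact p all hold, so the arrays cannot be told apart from the exposure. With the neutrophil minus T and NK level of each array as a covariate the interferon median was 0.23 (0.086 to 0.29, permutation p = 0.00866 for the mean level), while the mean level of secreted innate defence went from a change of 0.31 to 0.021. The neutrophil minus T and NK level was lowest on air replicates 1 and 2 (-0.82 and -0.88), both among the 3 arrays of lowest signal. On the other arrays it lay from -0.26 to 0.39, so it may follow array signal as well as cell share. The interferon values argue against a myeloid share as the whole cause of the interferon shift only as far as this level measures that share. A part due to the myeloid share, a share the level misses and the exposure stay open and untested. The neutrophil minus T and NK level itself was 0.38 higher in silica rats (exact p = 0.0952), 5 of the 15 neutrophil genes and 0 of the 22 T and NK genes stand on another list, and their most abundant genes were S100a8 (12.91 in air, 13.33 in silica blood) and Prf1 (11.47 and 11.79).

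For the other counts, 100 splits of the 12 rats into 6 and 6 were drawn with the real one included, and fewer than 5 of them gave as large a count as the real one for each count but that of the called probes in blood. In the lung 1 split gave as many called probes (2020, highest other 2), in BALF cells 1 (3187, 269), and for the tissue differences 1 each (2053 against 40 for lung and BALF cells, 713 against 1 for lung and blood, 1620 against 69 for BALF cells and blood). For gene lists 2 splits gave as many in the lung, where 1 other split also called as many lists as the real one (24, highest other 24), and 1 in BALF cells (16, 12). In blood the real split called 0 probes, a count that all 100 splits reach by necessity (highest other 2), so that nothing follows from it.

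In 49 of 448 groups of 6 arrays or rats, 1 lay far from the other 5, where chance gives about 22.4. Lung air replicate 3 stood above the other air arrays in log2 intensity for Spp1 (7.80), Slc26a4 (9.01), Ccl2 (8.11), Gpnmb (8.25), C1qc (9.74), C1qa (9.18), Cd83 (11.32) and RT1-Db1 (12.17) and below them for Xpnpep2 (10.10). BALF cell air replicate 4 stood above its group for Il1r2 (7.76), Slfn3 (8.42), Slpi (7.93), Chi3l1 (7.83), S100a8 (7.96) and Ifit1 (7.57), and its raw 95th percentile was 2901. BALF cell silica replicate 6 stood above its group for RT1-Db1 (13.18), RT1-Da (14.30), Cd74 (10.93), RT1-Ba (10.86), Ccl5 (10.80) and Cd3g (9.46) and below it for Ccl7 (9.64). Further arrays apart were lung silica replicate 6 for Il1rn (8.45) and Fdps (9.38), lung silica replicate 5 for Rrm2 (8.45), BALF cell air replicate 6 for Apoe (8.20), BALF cell silica replicate 3 for Ceacam4 (10.61) and Pf4 (12.26), blood silica replicate 6 for Ccr6 (7.56), and blood air replicate 4 (8.37) and silica replicate 5 (7.25) for Arg1. So were lung silica replicate 4 for Clock (7.47), lung air replicate 6 for Sftpc (14.00) and Usp2 (8.05), and blood air replicate 3 for Prf1 (11.12). Among differences of log2 values within a rat, silica rat 6 lay apart for lung minus BALF cells in RT1-Da (0.76) and RT1-Db1 (-0.059), for lung minus blood in Oasl2 (0.20), and for BALF cells minus blood in RT1-Db1 (2.49), RT1-Da (2.33), Cd74 (1.03) and Cfd (3.03). Air rat 4 lay apart for Slfn3 in lung minus BALF cells (2.83) and for Apoe in BALF cells minus blood (-1.54), and air rat 3 for Ccl2 in lung minus blood (0.84). For BALF cells minus blood, so did silica rat 4 for Hopx (-2.01), air rat 6 for Cd74 (-3.68) and silica rat 3 for Alox15 (-6.52).

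Effects that differed between tissues were tested within rats with limma. As above, a higher effect is a higher signed log2 change and can be a smaller fall. Fbp1, at -0.21 in the lung and -2.23 in BALF cells, changed more in BALF cells. So did Alox15, at -1.97 in BALF cells and -0.069 in blood. The effect was higher in the lung than in BALF cells for 1116 probes, led by Cfi (2.15), Fbp1 (2.02), Ly49s4 (1.76), Ubd (1.65), Gipc2 (1.59) and Heph (1.57), and lower for 937, led by Apoe (-4.35), Hopx (-3.42), RT1-Da (-2.81), RT1-Db1 (-2.76), Slfn3 (-2.74) and Il1r2 (-2.41). Against blood, 382 probes had a higher effect in the lung, led by Retnla (4.38), Ubd (2.62), Ccl2 (1.97), Igh-1a (1.77), Jchain (1.72) and Cd3g (1.43), and 331 a lower one, led by Mal (-1.28), Adgre5 (-1.15), Rgs3 (-1.08), Oasl2 (-1.04), Rtp4 (-1.01) and Gbp2 (-0.89). Of these, Cd3g, Oasl2, Rtp4 and Gbp2 passed in neither the lung nor blood by itself. In BALF cells 792 probes had a higher effect than in blood, led by Apoe (5.06), RT1-Db1 (3.53), RT1-Da (3.26), Ccl2 (3.18), Hopx (2.69) and Cd74 (2.25), and 828 a lower one, led by Alox15 (-1.90), Ly49s4 (-1.89), Zdhhc2 (-1.70), Fcgr3a (-1.42), Cfd (-1.32) and Ccdc80 (-1.30).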

How the results depend on the processing

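The shift to the median of detected probes, blood without 3 arrays and the covariance were chosen after the data were seen. Over all settings 4998 gene values kept their side of the threshold, 346 no longer passed, 4 newly passed and 3 reversed. For lists these were 1697, 95, 51 and 2. Direction was compared only where a value passed in the main or the other setting. Values that passed in neither count as kept and may have changed sign. Of the named tissue differences, which all passed in the main values, 220 values kept direction and side of the threshold and 28 no longer passed. With a median shift in place of quantile normalization, higher and lower calls were 37 and 40 in the lung, 275 and 207 in BALF cells, and for the differences 46 and 88 (lung and BALF cells), 3 and 1 (lung and blood) and 29 and 25 (BALF cells and blood). With the shift to the median of detected probes they were 322 and 659, 513 and 721, 422 and 424, 58 and 96, and 164 and 294. That shift reversed Slc4a1 (0.091) in the lung, Tekt1 (0.0041) and Tekt4 (0.011) in BALF cells and the direction of the T and NK list in blood (median -0.016), where 0 lists were then lower. Fewer calls were also made at a fold of at least 1.5 by its construction, 120 and 33 in the lung and 147 and 125 in BALF cells. Without background correction 220 probes had a lower effect in the lung than in blood, and without a filter 621 did. With probes detected on all 12 arrays the mast cell list of the lung reversed (-0.12) and 1 BALF cell list was lower. Without a filter 2 blood lists were lower. With an estimated correlation 2 lists were higher and 0 lower in the lung, and 0 and 0 in BALF cells and in blood. The joint model called 596 higher and 388 lower in blood. The covariances were 0.0126, 0.00142 and 0.0032 where the correlations had not passed. The cause of these changes was not tested.

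With the replicate number as a block, 603 lung probes were higher and 665 lower, and 1 BALF cell list was lower. Of the named genes, Igh-1a, Npy and Rnase3 did not pass in the lung with it. The calls of the alveolar type 1 and ciliated lists in BALF cells and of lipid handling in blood ended. The numbers do not pair silica with air rats: same-numbered arrays' deviations from their group means correlated at -0.40 to 0.33 in the lung, -0.20 to 0.39 in BALF cells and -0.49 to 0.32 in blood, and not every array correlated best with its own number.

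Leaving out each array gave 757 to 948 higher and 820 to 1100 lower probes in the lung and 1295 to 1482 and 1481 to 1720 in BALF cells. In blood it gave 0 higher and 0 to 1 lower (1 without air replicate 2). Called lists ranged over 18 to 19 higher and 5 to 8 lower in the lung, 13 to 14 and 1 to 3 in BALF cells (1 without air replicate 4) and 9 to 13 and 0 to 3 in blood (0 without silica replicate 6, 3 without air replicate 2). The slide as a block was not run, since the files name no slides. Raw signal was lowest in blood, with a 95th percentile of 514 to 1104, and fewer probes were above background and tested there (8044).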

Other observations

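Immunoglobulin probes, taken by their definitions in the files after Jchain and Igh-1a had been seen, were higher in silica lungs for 23 of 55 tested, with 0 lower, a median log2 change of 0.20 and a largest of 1.61, but with a median shift in place of quantile normalization 1 was higher and the median was 0.16. Over the other 3 scalings tried 23 to 31 were higher and 0 lower, with medians of 0.69 without background correction, 0.32 with the authors' processed values and 0.28 with the shift to the median of detected probes. In BALF cells 0 of 17 were higher and 1 lower, and in blood 0 of 45 passed, while the 1 lower probe of BALF cells did not pass with either median shift. Related immunoglobulin segments share sequence, so these probes are not independent of each other. Limma's test was the same as in the comparison of silica with air.

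Circadian clock genes, a list also chosen after the fall of Nr1d1 had been seen, differed in the lung beyond that gene. Bhlhe41 (0.92 ± 0.12), Cry1 (0.74 ± 0.15), Nfil3 (0.42 ± 0.088) and Bhlhe40 (0.42 ± 0.10), all repressors of transcription, rose, and Tef fell (-0.19 ± 0.046), while Per2 at -0.49 ± 0.19 did not pass (adjusted p = 0.0995), nor did Per1, Bmal1, Dbp, Clock, Npas2 and Usp2. All 5 and Nr1d1 kept their direction under the 4 other scalings, but with a median shift only Nr1d1 still passed (Cry1 0.50, Nfil3 0.25, Bhlhe40 0.18, Tef -0.24), and with the shift to the median of detected probes Bhlhe40 (adjusted p = 0.191) and Tef (0.357) did not pass. Per2 passed with the shift to the median of detected probes (-0.59, adjusted p = 0.034), and Usp2 without background correction (-0.34, adjusted p = 0.0291). The silica effect was higher in the lung than in BALF cells for Bhlhe41 (difference 0.86 ± 0.12), Bhlhe40 (0.74 ± 0.095), Nfil3 (0.59 ± 0.13) and Cry1 (0.46 ± 0.084). With a median shift none of these 4 differences passed (adjusted p from 0.231 to 0.65), and with the shift to the median of detected probes that of Cry1 did not (0.0814). The difference of Per2 was -0.88 with the shift to the median of detected probes (adjusted p = 0.00211) and -0.72 without background correction (0.00332). It was -0.59 with the authors' processed values (0.0143) and did not pass with a median shift (-0.96, adjusted p = 0.0902).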
